A study of Mus musculus with 77 samples.

How the data were processed

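Per the submitters' processing notes, reads were trimmed with Trimmomatic 0.32, aligned to mm10 with Bowtie2 2.3.4.1, freed of duplicates with Picard and turned into coverage with deepTools 3.5.1. Per the labels, 3 µg of antibody was used for H3K27me3 and H3K27ac and 1.5 µg for H2AK119Ub, and yeast DNA was added as a spike-in. The names of the deposited lists carry the SEACR terms norm and relaxed. The version, the control and any use of the spike-in for scaling are not given in the sources used here. The deposited lists, 1 per library, hold 6 columns with the position of each peak, its total signal, its highest signal and the place of the maximum. The unit, as deposited, is signal, a sum of coverage whose scale is not shown to be shared between lists. Mean signal on X is therefore given beside that on the autosomes of the same lists, and was not tested. The 77 lists held 883735 peaks.

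Peaks on the 19 autosomes and X were used. For each library the bases under peaks were divided by chromosome length (171.0 Mb of X, 2463 Mb of autosomes), and the X:autosome ratio is the log2 of the 2 shares. Groups were compared by exact two-sided permutation of libraries, within each system and time between genotypes and within each system and genotype between times, and pooled differences are means of the differences within strata. Benjamini-Hochberg values cover the 30 ratio comparisons. The genotype effect of the mb1-cre system at 0 h and 24 h and of the TAT-Cre system at 24 h was pooled, and the TAT-Cre cells at 0 h were kept apart as a baseline. One H3K27me3 library, mb1-cre Xist fl/fl 0 h replicate 5, is titled as naive and has a treatment entry of stimulated. It was grouped by its title, and moved to 24 h as an alternative.

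Genes came from the supplied table for GRCm38.p6, with 34328 genes (21631 protein-coding and 12697 long non-coding). A gene had a peak if a peak touched its body or the 2 kb on either side by at least 1 bp. The table has no strand, so windows around transcription starts were not used for any mark, including H3K27ac, for which they had been planned. Presence was compared by an exact conditional test in the same strata, among genes with a peak in at least 3 libraries and without one in at least 3, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. For stimulation, each list was first trimmed to the length of the shortest list of its mark by total signal (1955, 2004 and 1336 peaks for H3K27me3, H2AK119Ub and H3K27ac), because list length differed between times. Presence in a trimmed list is a rank within that list, not presence of the mark, so deposited counts are given beside it for many of the genes named. A gene without them may have had a deposited peak at both times. As another tool, limma 3.58.1 was run on the log2 of signal in ppm of autosomal peak signal plus 1. Simulated lists with 100 changed genes at log-odds shifts of 3 and 6 gave the recovery of the exact test. The changed genes were drawn from those with a peak in at least 6 libraries and without one in at least 6. Presence was drawn independently from each gene's rate and each library's list size. Recovery may therefore be lower for other genes tested.

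The genes named are the 10 with the smallest exact p in each direction for each mark and comparison, with ties broken by the larger difference, then X genes, then symbol; 12 fixed genes (Xist, Tsix, Jpx, Ftx, Tlr7, Cxcr3, Btk, Cd40lg, Kdm5c, Kdm6a, Ddx3x, Eif2s3x); and up to 4 members of each list. Genes outside the rule are said to be named after their values were seen, and some genes that the rule selects are not reported here. The 15 lists were the X inactivation centre (10 of 12 genes matched), mouse genes that escape X inactivation (14 of 14), X-linked immune genes (27 of 28), X-linked genes transcribed in most cells (32 of 32), follicular and mature B cell genes (31 of 33), B cell activation (37 of 37), cell cycle and ribosome biogenesis (24 of 24), plasma cell (12 of 12), developmental Polycomb targets (67 of 67), imprinted and long non-coding RNA domains (24 of 24), T cell (20), myeloid (18), NK cell (10) and erythroid (10) markers, and autosomal housekeeping genes (15). Tsix, Tasl, Ighm and Ighd had no match in the gene table. A list value is the log2 of the share of its genes with a peak over the share of all protein-coding genes with a peak, with 0.5 added to the counts. It was tested by exact stratified permutation with Benjamini-Hochberg adjustment over 90 tests.

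The groups, the comparisons, the tests, the naming rule and the alternatives were fixed before the data were examined, except where the text says that a choice was made after seeing the data. The alternatives were the upper 50% of each list by highest signal, the median over the 19 autosomes, replicate 5 at 24 h, no filter on libraries, trimmed or deposited lists, number of peaks, share of signal, an overlap of 500 bp, a reciprocal overlap of 50% or an overlap of 1 bp for replicate agreement, the highest 1% of peaks left out, limma, replicate number as a block, and each replicate left out. Added after seeing the data were H2AK119Ub lists of under 5000 peaks left out, the same with the others trimmed, either end of the gene with 2 kb each side, time permuted within genotype, the number of X genes at an unadjusted p under 0.05 in other splits, the number of genes at that p in trimmed lists, and the correlation of replicates of the same number between times. Peaks on Y and on unplaced sequences were left out. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9, and R 4.3.3, were used.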

Results

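Histone marks were profiled by CUT&RUN, in which an antibody tethers a nuclease that releases the DNA around the marked nucleosomes, in CD23+ B cells of the spleen of female mice. CD23 marks follicular B cells. The marks were H3K27me3 and H2AK119Ub, the repressive marks placed by the Polycomb complexes, and H3K27ac, a mark of active promoters and enhancers. Xist, the long non-coding RNA that coats and silences the inactive X chromosome, was removed by Cre recombinase in 2 systems. In the mb1-cre system Cre acts in the B lineage of the animal, and Xist fl/fl mice carrying mb1-cre were set against WT mice carrying mb1-cre. In the TAT-Cre system, B cells of Xist fl/fl and WT mice were given 80 µg of the cell-permeant enzyme for 45 min in culture. Cells were profiled unstimulated (0 h) or after 24 h with 1 µM CpG, a ligand of Toll-like receptor 9. The labels put TAT-Cre only before the 24 h culture, so the 0 h cells of that system were taken as a baseline with the floxed gene still in place.

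The 77 libraries fell into 24 groups of 3, except for H3K27me3 in the mb1-cre system, which had 4 WT and 5 Xist fl/fl libraries at 0 h and 4 of each at 24 h. Peak lists held 1955 to 19074 peaks per library for H3K27me3, 2004 to 40688 for H2AK119Ub and 1336 to 10393 for H3K27ac, and covered 29.2 to 209.8 Mb, 40.5 to 204.5 Mb and 20.0 to 121.7 Mb. Read depth is not given in the sources used here, so list length and depth cannot be told apart. Each library was summarised by its X:autosome ratio, the log2 of the share of chromosome X under peaks over the share of the 19 autosomes under peaks. This ratio compares X with the autosomes of the same library. The labels call the replicates biological without saying that each came from a separate animal, so p-values measure the spread between these samples.

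At Xist itself (mm10 X, 103460373 to 103483233), H2AK119Ub peaks covered 8.89% ± 11.8 (SD, n = 3) of the gene in mb1-cre WT cells at 24 h, with a peak in 3 of 3 libraries, and 0% in mb1-cre Xist fl/fl cells at 24 h, with a peak in 0 of 3. In the TAT-Cre system at 24 h the covered part was 12.3% ± 7.13 in WT and 14.5% ± 2.11 in Xist fl/fl cells, with a peak in 3 of 3 libraries of each. At 0 h, 2 of 3 libraries of every genotype and system had an H2AK119Ub peak there. No H3K27me3 library had a peak over Xist. H3K27ac peaks lay there in 1 of 3 libraries each of mb1-cre WT at 0 h, TAT-Cre WT at 24 h and TAT-Cre Xist fl/fl at 0 h, and in no library of the other groups. A list of peaks gives no count of the deleted allele, so these values do not check the deletion.

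The question of the genotype comparison was what B cells given Cre against Xist keep of the chromatin marks of the inactive X. H2AK119Ub on X was far lower in Xist fl/fl than in WT cells after 24 h of CpG. In the mb1-cre system the X:autosome ratio was −3.87 ± 0.11 (SD, n = 3) in Xist fl/fl and −0.74 ± 0.19 (n = 3) in WT cells, a difference of −3.13 ± 0.12 (SE), or 8.77-fold lower. In the TAT-Cre system it was −2.10 ± 0.16 against −0.42 ± 0.18, a difference of −1.68 ± 0.14, or 3.20-fold lower. H2AK119Ub peaks covered 0.265% of X in mb1-cre Xist fl/fl and 3.74% in WT cells at 24 h, and 1.31% and 3.98% in the TAT-Cre system. At 0 h the difference was −0.59 ± 0.24 in the mb1-cre system and 0.00 ± 0.33 in the TAT-Cre baseline before Cre.

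In both systems at 24 h, and in mb1-cre cells at 0 h, every Xist fl/fl library lay below every WT library. The exact two-sided permutation p was 0.1 for each of these, the smallest that 3 libraries against 3 can give, and 1 for the TAT-Cre baseline. Over the 3 comparisons with Cre together the difference was −1.80 ± 0.10, with an exact stratified permutation p of 0.00025, the smallest possible, and a Benjamini-Hochberg value of 0.0075 over 30 comparisons. That test permuted mb1-cre libraries of 0 h and 24 h separately. If both times came from the same animals, fewer splits would be possible and the smallest p would be larger. The covered length on X at 24 h was 0.453 Mb in mb1-cre Xist fl/fl and 6.39 Mb in WT cells, and 2.24 Mb and 6.81 Mb in the TAT-Cre system, while the autosomes had 94.7 and 151 Mb, and 135 and 129.8 Mb. The mean signal per covered base on X was 4.37 and 3.71 in the mb1-cre system and 3.31 and 2.83 in the TAT-Cre system, beside 4.27 and 4.42, and 3.64 and 3.34, on the autosomes of the same lists. With every list trimmed to 2004 peaks the pooled difference was −1.11 (exact permutation p = 0.00025) and the differences at 24 h were −1.88 in the mb1-cre and −0.64 in the TAT-Cre system. At 0 h, 4 H2AK119Ub lists held only 2004 to 2804 peaks (2 mb1-cre WT, 1 mb1-cre Xist fl/fl, 1 TAT-Cre WT), and with them left out, a choice made after seeing the data, the pooled difference was −1.92 (8 against 7 libraries, with 1 mb1-cre WT library left at 0 h, exact permutation p = 0.000833).

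**Figure D1:**
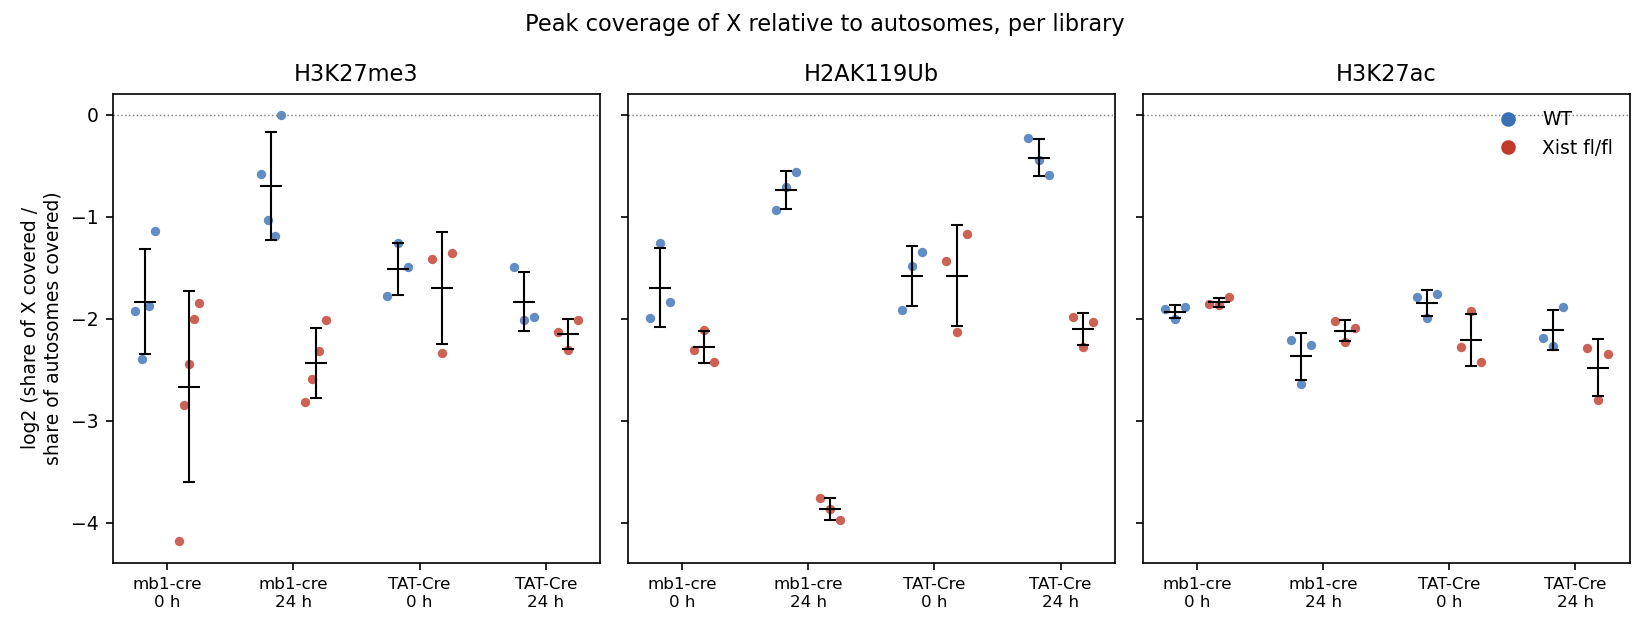
X:autosome ratio of peak coverage (log2, vertical axis) for each library, by mark, system, genotype and time; points are libraries and bars are group means ± SD. At 24 h the H2AK119Ub groups were at −3.87 (mb1-cre Xist fl/fl), −0.74 (mb1-cre WT), −2.10 (TAT-Cre Xist fl/fl) and −0.42 (TAT-Cre WT).

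Along X, the strip from 100 to 105 Mb, which holds Xist, was the 5-Mb window with the widest H2AK119Ub coverage in WT cells at 24 h, 27.1% in the mb1-cre system and 21.6% in the TAT-Cre system. In Xist fl/fl cells the same window held 0.646% and 7.74%. The window from 90 to 95 Mb went from 14.5% in mb1-cre WT to 1.22% in Xist fl/fl cells, and from 11.1% to 5.92% in the TAT-Cre system. The window from 10 to 15 Mb, which holds Bcor, kept more, with 3.86% and 2.32% in the mb1-cre system and 3.58% and 3.06% in the TAT-Cre system. Of 35 windows, all Xist fl/fl libraries lay below all WT libraries in 23 in the mb1-cre system and in 22 in the TAT-Cre system at 24 h, and above them in 0. Such a separation of 3 from 3 libraries has an exact two-sided permutation p of 0.1 in a single window. At 0 h it was 1 window in the mb1-cre system and 0 in the TAT-Cre baseline. Window coverage was not set against the autosomes, on which mb1-cre H2AK119Ub peaks at 24 h covered 94.7 Mb in Xist fl/fl and 151 Mb in WT cells. For H3K27ac at 24 h the same separation held in 14 windows in TAT-Cre cells, where the Xist fl/fl lists were shorter. In mb1-cre cells it held in 1 window, with 2 the other way.

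**Figure D2:**
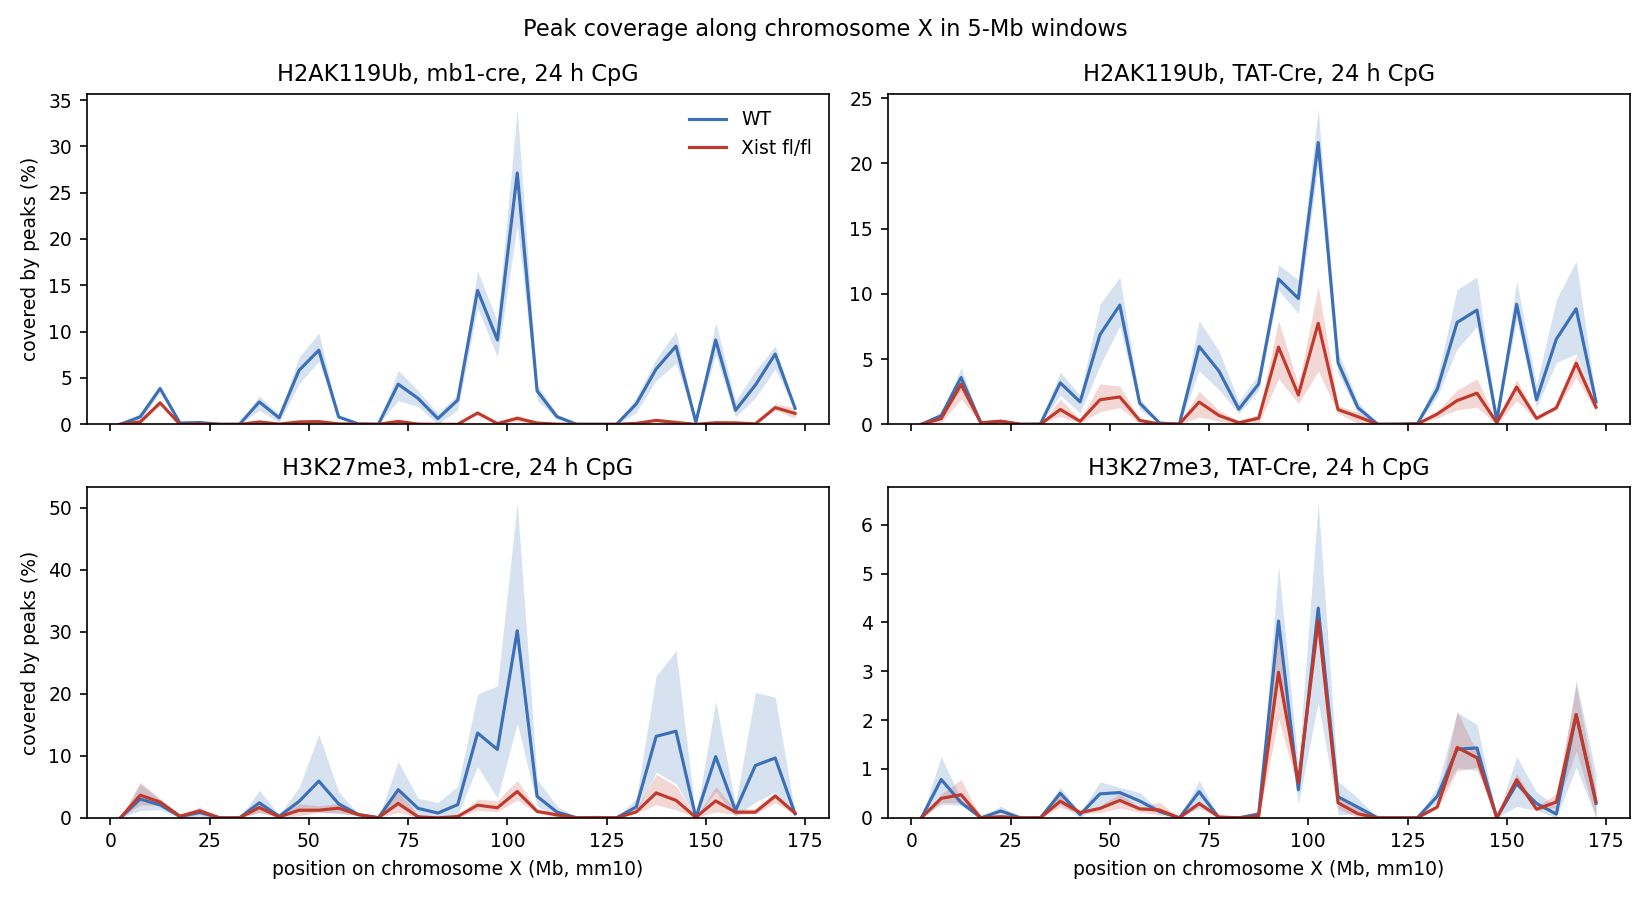
Percent of each 5-Mb window covered by peaks (vertical axis) along chromosome X (Mb, horizontal axis) at 24 h for H2AK119Ub and H3K27me3 in both systems; lines are group means, shading runs from the lowest to the highest library, and the vertical axes differ between panels. The window from 100 to 105 Mb held 27.1% H2AK119Ub coverage in mb1-cre WT and 0.646% in Xist fl/fl cells.

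Among the 966 protein-coding genes on X, 28.2% ± 7.46 (SD, n = 3) had an H2AK119Ub peak in mb1-cre WT cells at 24 h and 3.38% ± 1.97 in Xist fl/fl cells. In the TAT-Cre system these were 37.4% ± 3.76 and 17.9% ± 3.69. Autosomal genes had 50.0% and 39.9%, and 54.6% and 51.0%. In the mb1-cre system 143 X genes had a peak in all 3 WT libraries, and 94 of them (65.7%) had one in no Xist fl/fl library, against 3.25% of 7732 autosomal genes. In the TAT-Cre system it was 47 of 231 X genes (20.3%) against 1.27% of 8440. Over both systems, 9 X genes kept a peak in all 12 libraries at 24 h, among them Bcor, Sowahd, Tmem255a, Cldn34d, Cited1, Esx1, Map7d2 and Mid1. They were named after their values were seen.

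Genes with the smallest p and fewer H2AK119Ub peaks in Xist fl/fl cells included X genes, which the naming rule puts first among ties. 9530027J09Rik, Col4a5, a type IV collagen gene, Gm41898 and Rbm41 had a peak in 0 of 9 Xist fl/fl and 7 of 9 WT libraries, as did the autosomal gene Aldh1l1 (exact stratified p = 0.0025, Benjamini-Hochberg adjusted p = 1). Jpx, a non-coding activator of Xist, had a peak in 1 of 9 against 8 of 9 (exact p = 0.004) and Zcchc13 in 3 of 9 against 9 of 9 (exact p = 0.005). The autosomal genes A830035O19Rik, Itpkc and Lrwd1 had 0 of 9 against 6 of 9. The genes with the smallest p and more peaks included Anapc13 (5 of 9 against 0 of 9, exact p = 0.02), Apba3, Mrpl54 and Pcolce (exact p = 0.05). Of the fixed genes, Tlr7, a nucleic acid receptor of B cells, had 0 of 9 against 4 of 9 (exact p = 0.05), Kdm6a and Cxcr3 each had 2 of 9 against 6 of 9, Xist had 5 of 9 against 8 of 9, Eif2s3x had 2 of 9 against 5 of 9, Ftx had 6 of 9 against 9 of 9, Kdm5c had 3 of 9 against 4 of 9, Btk and Cd40lg had 0 of 9 against 2 of 9, and Ddx3x had none. No gene of 16824 passed the exact test after adjustment, 177 had an unadjusted p under 0.05, and limma called 0. Of the 177, 176 had fewer peaks in Xist fl/fl cells and 1 had more. On X, which held 481 of the 16824 genes tested, 81 had such a p, all with fewer peaks. In trimmed lists 26 genes of all chromosomes had an unadjusted p under 0.05, 15 with fewer and 11 with more. On simulated lists of this size the same test recovered 0 of 100 changed genes at either of 2 sizes of change, so the 0 does not show that no gene changed.

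Of the 15 fixed gene lists, 5 differed in H2AK119Ub between genotypes, measured as the log2 of the share of a list's genes with a peak over the share of all protein-coding genes. X-linked genes transcribed in most cells fell by 2.11 ± 0.27 (SE, 9 against 9 libraries, adjusted exact permutation p = 0.00413 over 90 tests), from 39.6% to 1.04% of 32 members with a peak in mb1-cre cells at 24 h. Rps4x, a ribosomal protein gene, had 0 of 9 against 5 of 9, Taf1 2 of 9 against 7 of 9, and Ogt 0 of 9 against 5 of 9. The X inactivation centre fell by 1.38 ± 0.31 (adjusted exact p = 0.00413), with Rlim, a ubiquitin ligase that acts on Xist's repressor, at 0 of 9 against 6 of 9 and Tsx at 2 of 9 against 7 of 9. Genes known to escape X inactivation in mouse fell by 0.97 ± 0.21 (adjusted exact p = 0.00865), with Pbdc1 at 2 of 9 against 7 of 9 and Car5b at 1 of 9 against 4 of 9. X-linked immune genes, of which the member Il9r lies on chromosome 11, differed by −0.9998 ± 0.17 (adjusted exact p = 0.0129), with Msn at 0 of 9 against 6 of 9, but the difference was 0.09 in trimmed lists. Imprinted and long non-coding RNA domains were higher by 0.32 ± 0.14 (adjusted exact p = 0.0439) and at −0.20 in trimmed lists. No member of these lists passed over all genes tested (0 of 10, 11, 15, 16 and 14 tested members of the X inactivation centre, escape, immune, broadly transcribed and imprinted lists). Adjusted over the list alone, 3 X inactivation centre members and 1 escape gene passed, all with fewer peaks. Jpx and Ftx belong to both of these lists, and Xist belongs to the escape list, so the list values are not independent.

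H3K27me3 on X was also lower in Xist fl/fl than in WT cells given Cre. In the mb1-cre system at 24 h the X:autosome ratio was −2.43 ± 0.34 (SD, n = 4) in Xist fl/fl and −0.70 ± 0.53 (n = 4) in WT cells, a difference of −1.73 ± 0.32 (SE), or 3.33-fold lower, with no overlap between the genotypes. At 0 h it was −2.66 ± 0.94 (n = 5) and −1.83 ± 0.52 (n = 4), a difference of −0.83 ± 0.49. In the TAT-Cre system at 24 h it was −2.15 ± 0.15 (n = 3) and −1.83 ± 0.29 (n = 3), a difference of −0.32 ± 0.19, with the nearest libraries of the genotypes at −2.014 and −2.012, and −0.15 without WT replicate 1 (exact permutation p = 0.2). At baseline the difference was −0.19 ± 0.35. H3K27me3 covered 1.24% of X in mb1-cre Xist fl/fl and 4.29% in WT cells at 24 h.

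The exact permutation p was 0.0286 for mb1-cre at 24 h, the smallest possible (Benjamini-Hochberg value 0.107 over 30), 0.135 for mb1-cre at 0 h, 0.1 for TAT-Cre at 24 h, the smallest possible, and 0.7 for the baseline. Over the 3 comparisons with Cre the difference was −0.96 ± 0.20 (12 against 11 libraries, exact stratified permutation p = 0.000544, Benjamini-Hochberg value 0.00816). Here too the mb1-cre libraries of 0 h and 24 h were permuted as separate samples. The covered length on X was 2.11 against 7.34 Mb for mb1-cre at 24 h, 1.56 against 1.90 Mb at 0 h and 0.853 against 0.999 Mb for TAT-Cre at 24 h. Autosomes had 156 against 151 Mb, 102 against 85.8 Mb and 54.3 against 49.3 Mb. The mean signal per covered base on X was 6.15 against 5.51, 8.30 against 7.88 and 4.36 against 5.37, beside 7.83 against 7.55, 11.04 against 9.53 and 5.17 against 6.47 on the autosomes of the same lists. In lists trimmed to 1955 peaks the differences were −1.11 for mb1-cre at 0 h (exact permutation p = 0.0159), −2.30 for mb1-cre at 24 h and −0.93 for TAT-Cre at 24 h. The replicate 5 library of mb1-cre Xist fl/fl cells is titled as 0 h but carries a stimulation entry, and with it moved to 24 h the differences were −1.04 at 0 h (exact permutation p = 0.0571) and −1.62 at 24 h (exact permutation p = 0.00794).

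Genes with fewer H3K27me3 peaks in Xist fl/fl cells were led by X genes: Gm33605 (0 of 12 against 5 of 11 libraries, exact p = 0.00635), Zfx (6 of 12 against 11 of 11, exact p = 0.0102), G530011O06Rik (2 of 12 against 8 of 11), Frmpd4 (0 of 12 against 5 of 11), Tsx, next to Xist (3 of 12 against 9 of 11, exact p = 0.0166), the chromosome 8 gene Gm51530 (7 of 12 against 11 of 11, exact p = 0.025), and Ogt, Scml1 and Stard8 (each 0 of 12 against 4 of 11, exact p = 0.0286). The genes with the smallest p and more peaks were the autosomal Arhgef11 (12 of 12 against 3 of 11, exact p = 0.00051), Itpr2 (10 of 12 against 2 of 11, exact p = 0.00204), Acot1, Celsr2 and Slc34a1 (each 11 of 12 against 4 of 11, exact p = 0.00238). The adjusted p of each was 1. Of the fixed genes, Kdm5c and Eif2s3x each had 1 of 12 against 4 of 11, Ftx had 2 of 12 against 3 of 11, Cd40lg had 0 of 12 against 1 of 11, and the others had no peak. No gene of 7789 passed the exact test, 149 had an unadjusted p under 0.05 (129 with more and 20 with fewer peaks, 13 of the latter on X; in trimmed lists 25 and 46), and limma called 1, the X gene Klhl15, with less signal. In trimmed lists 4 X genes passed: Klhl15 and Gspt2 (each 1 of 12 against 11 of 11, adjusted exact p = 0.0353), Zfx and Nup62cl (each 0 of 12 against 9 of 11, adjusted exact p = 0.0441). Klhl15, Gspt2 and Zfx lie between 94074631 and 94638562 on X. Those other than Zfx were named after their values were seen. On simulated lists the test recovered 10% and 85% of changed genes at log-odds shifts of 3 and 6.

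X-linked genes transcribed in most cells was the only 1 of 15 lists to change in H3K27me3 between genotypes. It fell by 1.29 ± 0.22 (SE, 12 against 11 libraries, adjusted exact permutation p = 0.00408), from 14.1% to 1.56% of its 32 members with a peak in mb1-cre cells at 24 h. 0 of its 3 tested members passed over all genes, and 2 passed adjusted over the list alone, both with fewer peaks. X-linked immune genes were at −0.52 ± 0.19 (adjusted exact p = 0.0505) and the X inactivation centre at −0.50 ± 0.18 (adjusted exact p = 0.118; −1.96 and 0.00372 in trimmed lists).

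H3K27ac on X did not differ between genotypes over the 3 comparisons together (−0.01 ± 0.08 SE, 9 against 9 libraries, exact stratified permutation p = 0.956). By system it went in opposite directions. In mb1-cre cells the Xist fl/fl minus WT difference was 0.09 ± 0.04 at 0 h and 0.25 ± 0.15 at 24 h. In TAT-Cre cells it was −0.36 ± 0.17 at baseline, before Cre, and −0.37 ± 0.20 at 24 h. The exact permutation p was 0.1, 0.2, 0.2 and 0.1, where 0.1 is the smallest possible. At 24 h peaks covered 1.57 Mb of X in mb1-cre Xist fl/fl and 1.32 Mb in WT cells, and 0.547 and 1.16 Mb in the TAT-Cre system, with 97.3 and 97.6 Mb, and 42.4 and 70.7 Mb, of autosomes. The mean signal per covered base on X was 7.98 and 7.26, and 6.33 and 7.07, beside 9.10 and 8.50, and 7.83 and 8.65, on the autosomes of the same lists.

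No gene of 6420 passed for H3K27ac (exact test), 70 had an unadjusted p under 0.05, limma called 0, and the test recovered 2% and 36% of changed genes on simulated lists. All 70 had fewer peaks in Xist fl/fl cells and 1 was on X, but the TAT-Cre Xist fl/fl lists at 24 h were also shorter (3669 to 6244 peaks against 5456 to 10009). In trimmed lists 27 had such a p, 23 with fewer and 4 with more. The genes with the smallest p and fewer peaks in Xist fl/fl cells included Gm51712 and Ptbp2, a splicing regulator (each 3 of 9 against 9 of 9, exact p = 0.005), Socs3, an inhibitor of cytokine signalling (1 of 9 against 7 of 9, exact p = 0.01), and Crip1 (2 of 9 against 8 of 9, exact p = 0.016). Those with the smallest p and more peaks included Gm42150 (5 of 9 against 1 of 9, exact p = 0.095) and Cdc14b, Fam185a and Usp45 (each 3 of 9 against 0 of 9, exact p = 0.1). Tlr7, Btk, Kdm6a and Ftx had a peak in 9 of 9 libraries of either genotype, Jpx in 4 of 9 against 6 of 9, Ddx3x in 5 of 9 against 6 of 9, Kdm5c in 4 of 9 against 5 of 9 and Eif2s3x in 4 of 9 each. None of the 15 lists passed for H3K27ac between genotypes, the erythroid markers coming nearest at 0.43 ± 0.16 (adjusted exact permutation p = 0.0788).

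Against the other chromosomes, X had the largest genotype difference of the 20 for H3K27me3 and H2AK119Ub in every comparison with Cre. For H2AK119Ub in mb1-cre cells at 24 h the autosomes lay between −0.12 and 0.14, where X was at −3.13, and in TAT-Cre cells between −0.05 and 0.06, where X was at −1.68. For H3K27me3 in mb1-cre cells at 24 h they lay between −0.04 and 0.05, where X was at −1.73. In the TAT-Cre baseline, before Cre, X ranked 19 of 20 for H2AK119Ub but 1 of 20 for H3K27me3 (−0.19, autosomes −0.12 to 0.11) and for H3K27ac (−0.36, autosomes −0.11 to 0.07). For H3K27ac it also ranked 1 of 20 in mb1-cre cells at 0 h and 24 h and in TAT-Cre cells at 24 h, and 18 of 20 over the 3 comparisons with Cre, where the signs differ between systems.

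**Figure D3:**
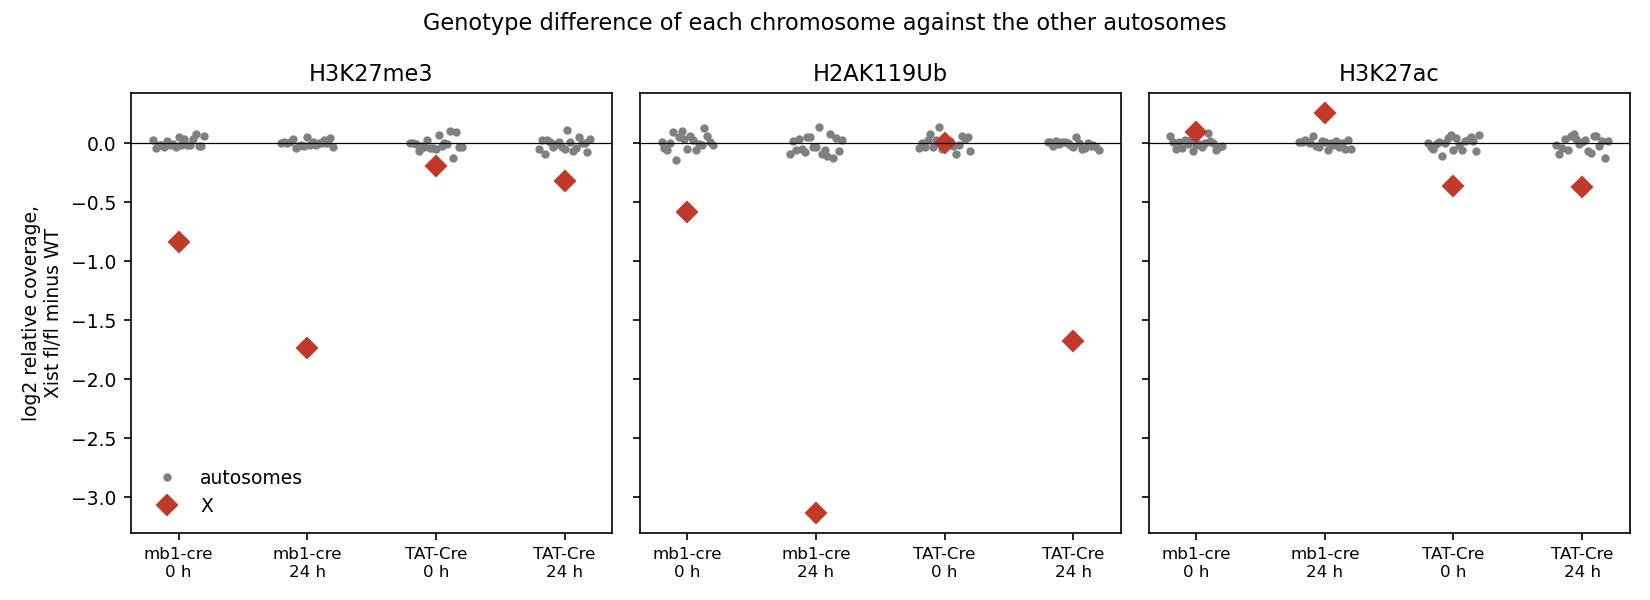
Genotype difference (Xist fl/fl minus WT, log2 ratio of peak coverage against the other autosomes, vertical axis) of each chromosome, by mark. The horizontal axis gives the system and time, and TAT-Cre at 0 h is the baseline before Cre. Grey points are autosomes and the diamond is X. In the comparisons with Cre together, which are not drawn, X was at −0.96 for H3K27me3, −1.80 for H2AK119Ub and −0.01 for H3K27ac. The autosomes then lay between −0.07 and 0.09.

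The genotype difference at 24 h was compared with that at 0 h. In the mb1-cre system both times lie after deletion, while in the TAT-Cre system the 24 h cells differ from the 0 h cells in Cre as well as in CpG and culture, so the value there holds the deletion itself. For H2AK119Ub it was −2.55 ± 0.27 (SE) in the mb1-cre system and −1.68 ± 0.36 in the TAT-Cre system. In WT cells the X:autosome ratio was higher at 24 h than at 0 h by 0.96 and 1.16, and in Xist fl/fl cells it was lower at 24 h, by −1.59 and −0.52. The exact permutation p was 0.1 and 0.05 with genotypes permuted within times. It was 0.005 and 0.015 with times permuted within genotypes, a test chosen after seeing the data. In trimmed lists these values were −1.07 (exact permutation p = 0.26 with genotypes and 0.02 with times permuted) and −0.57 (0.115 and 0.27). The changes from 0 h to 24 h in trimmed lists were 0.20 and −0.37 in WT cells and −0.87 and −0.94 in Xist fl/fl cells. The rise in TAT-Cre WT cells was thus reversed there. For H3K27me3 the deposited lists gave −0.90 ± 0.58 (exact permutation p = 0.341) and −0.13 ± 0.40 (0.77), and the trimmed lists −1.19 ± 0.49 (0.271, and 0.0303 with times permuted) and −1.08 ± 0.60 (0.135, and 0.145 with times permuted). For H3K27ac the deposited lists gave 0.16 ± 0.16 (0.51) and −0.01 ± 0.26 (0.98).

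The systems differed in Cre, in culture history and in the time since deletion. At 24 h the H2AK119Ub genotype difference was larger in mb1-cre than in TAT-Cre cells by −1.46 ± 0.19 (exact permutation p = 0.465, a test that permutes genotypes and so is blunt where both systems differ strongly). For H3K27me3 it was −1.41 ± 0.37 (exact permutation p = 0.0543). For H3K27ac the difference between systems was 0.62 ± 0.25 (exact permutation p = 0.01, Benjamini-Hochberg value 0.06).

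Stimulation for 24 h was compared with 0 h within each genotype and system. The 24 h cells of both genotypes in the TAT-Cre system had also been given TAT-Cre, so in Xist fl/fl cells stimulation and Cre are confounded there. This holds for every pooled stimulation value of X, genes and lists. In WT cells the H2AK119Ub ratio of X was higher by 1.06 ± 0.16 (SE, 6 against 6 libraries, exact stratified permutation p = 0.005, the smallest possible, Benjamini-Hochberg value 0.05), and in Xist fl/fl cells lower by −1.05 ± 0.16 (exact p = 0.015, value 0.075). Autosomes moved by −0.58 to 0.49 over the same libraries in WT cells. In trimmed lists the WT difference was −0.09 (exact permutation p = 0.545) and in lists of at least 5000 peaks it was 0.75 (exact p = 0.025, 6 against 3 libraries). The H3K27me3 ratio differed by 0.40 ± 0.22 in WT (exact p = 0.189) and −0.11 ± 0.28 in Xist fl/fl cells (exact p = 0.75; −0.75 and 0.0313 in trimmed lists). The deposited values average systems of opposite sign, 1.13 in mb1-cre and −0.32 in TAT-Cre WT cells, and 0.23 and −0.45 in Xist fl/fl cells. The H3K27ac ratio was lower in WT by −0.35 ± 0.10 (exact p = 0.01, value 0.06) and in Xist fl/fl cells by −0.28 ± 0.11 (exact p = 0.02, value 0.0857). In the upper 50% of each list these were 0.11 and 0.59, the opposite direction, and by share of signal −0.21 (exact p = 0.06) and −0.16 (0.205). By number of peaks they were −0.09 (exact p = 0.32) and −0.13 (0.335). In deposited lists the Xist fl/fl value had an exact p of 0.08 without TAT-Cre Xist fl/fl 0 h replicate 2 and 0.065 without the 24 h replicate 2 of that genotype.

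Stimulation was compared over single genes in lists trimmed to 1 length, because longer lists touch more genes. A gene then counts as having a leading peak when it has a peak among the strongest 1336 of a library for H3K27ac (2004 for H2AK119Ub, 1955 for H3K27me3). A gain or loss is therefore a change of rank within a list, and a gene that lost its leading peak can still have a peak in the deposited list. Trimming equalises the number of peaks, not their width, which also changes how many genes are touched. In deposited mb1-cre WT lists of H2AK119Ub the median width was 3287.5 to 14531 bp at 0 h and 3483 to 7223 bp at 24 h. In TAT-Cre Xist fl/fl lists of H3K27ac it was 3647 to 12756 bp and 6446 to 6936.5 bp. Among 1753 genes tested for H3K27ac, 260 gained and 239 lost a leading peak (exact test), and in deposited lists 2458 gained and 25 lost a peak, 75 of the genes being called in both. Batf, a transcription factor of B cell activation, had a leading peak in 12 of 12 libraries at 24 h and 0 of 12 at 0 h (exact stratified p = 1.25e-05, adjusted p = 0.000466), and in deposited lists a peak in 12 of 12 and 1 of 12. Fut8 (deposited 12 of 12 and 3 of 12), Gnat3 (12 of 12 and 5 of 12), Eno3 (12 of 12 and 8 of 12), Agpat4, Ahcyl2 and Cd36 (each 12 of 12 and 9 of 12) had the same leading counts. Ipcef1 and 1700113H08Rik went from 12 of 12 to 0 of 12 leading peaks and had a deposited peak at 24 h in 12 of 12 and 11 of 12. Of 10 tested B cell activation genes 3 gained and 1 lost a leading peak and 6 did not pass, with 3 and 1 adjusted over the list alone. Cd69, an early activation antigen, gained (2 of 12 to 11 of 12, adjusted exact p = 0.0061), as did Nfkbia, the inhibitor of NF-κB (0 of 12 to 6 of 12, adjusted exact p = 0.037). In deposited lists at 0 h Cd69 already had a peak in 2 or 3 of the 3 libraries of each group, and Nfkbia in 1 to 3. Egr1, an immediate early gene, lost its leading peak (8 of 12 to 0 of 12, adjusted exact p = 0.00877), with a deposited peak in 10 of 12 and 9 of 12.

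On X, 5 genes lost a leading H3K27ac peak and 0 gained 1, but the mark was still called there. Kdm6a, an H3K27 demethylase gene that escapes X inactivation, went from 10 of 12 leading peaks to 0 of 12 (adjusted exact p = 0.00225), with a deposited peak in 11 of 12 libraries at 0 h and 12 of 12 at 24 h. Tlr7 went from 11 of 12 to 4 of 12 (adjusted exact p = 0.0333) and Tsc22d3, a glucocorticoid-induced gene, from 12 of 12 to 0 of 12 (adjusted exact p = 0.000466), each with a deposited peak in 12 of 12 at both times. The others were Gm39538 and Gm39549, named after their values were seen. Btk, a kinase of B cell receptor signalling, had a leading peak in 12 of 12 and 8 of 12 (adjusted exact p = 0.164). Of the autosomal housekeeping genes Rpl13a gained a leading peak (5 of 12 to 12 of 12, adjusted exact p = 0.0333), 3 tested members did not pass, and 2 passed adjusted over the list alone. Escape genes had 1 of 2 tested members with a lost leading peak (Kdm6a) and X-linked immune genes 1 of 5 (Tlr7).

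For H2AK119Ub, 750 of 4306 genes tested gained and 497 lost a leading peak on stimulation (exact test), and in deposited lists 2017 gained and 29 lost a peak, 117 of the genes being called in both. Genes with a leading peak in 12 of 12 libraries at 24 h and 0 of 12 at 0 h included the developmental regulators Foxa1, Fev, Dmrta2 and Nkx6-1, and Cryba2, Entpd2 and Fhdc1 (exact stratified p = 1.25e-05, adjusted p = 0.000758). In deposited lists these had a peak in 12 of 12 at 24 h and in 7 or 8 of 12 at 0 h. Leading peaks went from 12 of 12 to 0 of 12 at Acbd7, Ankrd50, Antxr2, Capsl, Chrm3, a muscarinic receptor, and Cyb5r4. In deposited lists Ankrd50 still had a peak in 12 of 12 libraries at 24 h, Acbd7, Antxr2, Capsl and Chrm3 in 11 of 12 and Cyb5r4 in 7 of 12. Of 12 tested developmental Polycomb targets 8 gained a leading peak, 0 lost 1 and 4 did not pass, and 9 gained adjusted over the list alone. They were Hoxd4, Wt1, Nkx6-1, Sox1, Nkx2-1, Foxa1, Olig2 and Pax2, with Pax2 going from 2 of 12 to 12 of 12 and Wt1 from 0 of 12 to 10 of 12 (adjusted exact p = 0.00208 and 0.00225). Hoxd4, Sox1, Nkx2-1 and Olig2 were named after their values were seen. Of 5 tested follicular and mature B cell genes 2 gained, with 2 adjusted over the list alone, Spib (0 of 12 to 10 of 12, adjusted exact p = 0.00208; deposited 5 of 12 to 12 of 12) and Cd37 (0 of 12 to 6 of 12, 0.0365). Of 9 tested B cell activation genes Egr3, Nr4a1 and Nfkb2 gained a leading peak and Il10 lost it, though Il10 had a deposited peak in 12 of 12 at both times. Adjusted over the list alone 4 gained and 1 lost.

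Other lists had members whose leading H2AK119Ub peaks went both ways. Tcf7, a T cell transcription factor, gained (2 of 12 to 12 of 12) and Il7r lost (12 of 12 to 2 of 12; adjusted exact p = 0.00225 each), with a deposited Il7r peak in 11 of 12 at 24 h. Among myeloid markers Cebpb gained (0 of 12 to 10 of 12) and Adgre1 lost (11 of 12 to 0 of 12; deposited 10 of 12 at 24 h), and among erythroid markers Klf1 gained and Hbb-bs lost. The imprinted genes Plagl1 and Mest lost a leading peak, each with a deposited peak in 12 of 12 at 24 h, as did Dnajb9 of the plasma cell list (deposited 11 of 12 to 5 of 12) and Npm1 of the cell cycle and ribosome biogenesis list, which had no difference in deposited lists. On X, Chic1 of the X inactivation centre gained (0 of 12 to 6 of 12, adjusted exact p = 0.0365), as did Cldn34d. The leading peaks of Chic1 at 24 h were in 3 of 3 mb1-cre and 2 of 3 TAT-Cre WT libraries, and in 0 of 3 and 1 of 3 Xist fl/fl libraries. In deposited lists Chic1 had a peak at 24 h in 3 of 3 WT libraries of each system. It had one in 2 of 3 mb1-cre and 3 of 3 TAT-Cre Xist fl/fl libraries. H2al1o, Cask, Tmem255a, Fgf16, Fndc3c1, Dach2 and Trpc5 lost a leading peak, Trpc5 going from 11 of 12 to 0 of 12 (adjusted exact p = 0.000992). The X genes other than Chic1 were named after their values were seen. Adjusted over the list alone, 1 T cell, 1 myeloid and 1 erythroid marker gained and 1 of each lost, and 3 imprinted genes, 1 plasma cell gene and 1 cell cycle gene lost.

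For H3K27me3, 16 of 3431 genes tested gained and 28 lost a leading peak on stimulation (exact test). None of them was on X, but only 40 of the genes tested were X genes. The calls depend on the setting: 0 genes passed in deposited lists, 0 with replicate number as a block, 9 with no filter on libraries and 103 by limma. Without mb1-cre Xist fl/fl 0 h replicate 4 the count was 28 against 44 with it. Scfd2 went from 15 of 15 leading peaks to 1 of 14 and Zfp811 from 14 of 15 to 0 of 14 (exact stratified p = 1.13e-06, adjusted p = 0.000973), while in deposited lists they had a peak at 24 h in 14 of 14 and 13 of 14. Atf3, a stress-response transcription factor, went from 15 of 15 to 2 of 14 (adjusted exact p = 0.00259; deposited 12 of 14 at 24 h). Rgs13, a regulator of G protein signalling found in germinal centre B cells, went from 12 of 15 to 0 of 14 (adjusted exact p = 0.00432; deposited 14 of 15 and 5 of 14). Leading peaks were gained at Tox2 (0 of 15 to 9 of 14, adjusted exact p = 0.0169), Amotl2 (0 of 15 to 11 of 14, 0.00849) and Npas3 (4 of 15 to 14 of 14, 0.0151), with deposited peaks at 0 h in 13 of 15, 11 of 15 and 11 of 15. Of 5 tested B cell activation genes 0 passed and 1 lost adjusted over the list alone, Cd86 having 10 of 15 and 2 of 14 (adjusted exact p = 0.223 over all genes).

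Of the list values, taken on lists as deposited, 2 differed between 24 h and 0 h for H3K27me3, 5 for H2AK119Ub and 8 for H3K27ac. For H2AK119Ub, the follicular and mature B cell list rose by 2.07 ± 0.30 (12 against 12 libraries, adjusted exact permutation p = 0.000778), from 11.8% to 73.1% of 31 members in mb1-cre WT cells. In the same libraries the share of autosomal protein-coding genes with a peak went from 25.3% to 50.0%. Their lists held 2179, 2804 and 40688 peaks at 0 h and 14806 to 32632 at 24 h. B cell activation rose by 0.21 ± 0.07 (adjusted exact p = 0.036), escape genes fell by 0.79 ± 0.16 (adjusted exact p = 0.00408) and the X inactivation centre by 0.63 ± 0.23 (adjusted exact p = 0.0158; 0.416 in trimmed lists). Autosomal housekeeping genes were at 1.74 ± 0.29 (adjusted exact p = 0.00169) but at −0.38 in trimmed lists (adjusted exact p = 0.00197). For H3K27me3, B cell activation fell by 0.93 ± 0.14 (14 against 15 libraries, adjusted exact p = 0.000778), from 16.2% to 5.41% of 37 members in TAT-Cre WT cells and with 15.5% and 16.2% in mb1-cre WT cells. Cell cycle and ribosome biogenesis genes fell by 0.89 ± 0.19 (adjusted exact p = 0.0196).

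For H3K27ac, escape genes fell by 0.42 ± 0.09 (12 against 12 libraries, adjusted exact p = 0.00225) and X-linked immune genes by 0.73 ± 0.16 (0.00169). T cell markers fell by 0.55 ± 0.16 (adjusted exact p = 0.00413) and developmental Polycomb targets by 0.92 ± 0.29 (0.0271). The fall of the T cell list is relative to all genes and does not measure other lymphocytes in the sort. The follicular and mature B cell list fell by 1.02 ± 0.25 (adjusted exact p = 0.00413) and imprinted domains by 0.66 ± 0.12 (0.00413), at −0.12 and −0.10 in trimmed lists. B cell activation was at −0.51 ± 0.17 (adjusted exact p = 0.0235) and X-linked genes transcribed in most cells at 0.81 ± 0.27 (0.018), but at 0.18 and −0.23 in trimmed lists. These values are relative to all genes: 100% of the 31 follicular genes had an H3K27ac peak in mb1-cre WT libraries at 0 h and at 24 h, while the share of autosomal genes with a peak went from 17.8% to 32.2%. The plasma cell list (nearest H2AK119Ub, −0.49 ± 0.22, adjusted exact p = 0.115), myeloid markers (H3K27me3, −0.13 ± 0.07, 0.183) and NK cell markers (H2AK119Ub, −0.44 ± 0.26, 0.224) passed in no mark in either comparison, nor did the erythroid markers.

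**Figure D4:**
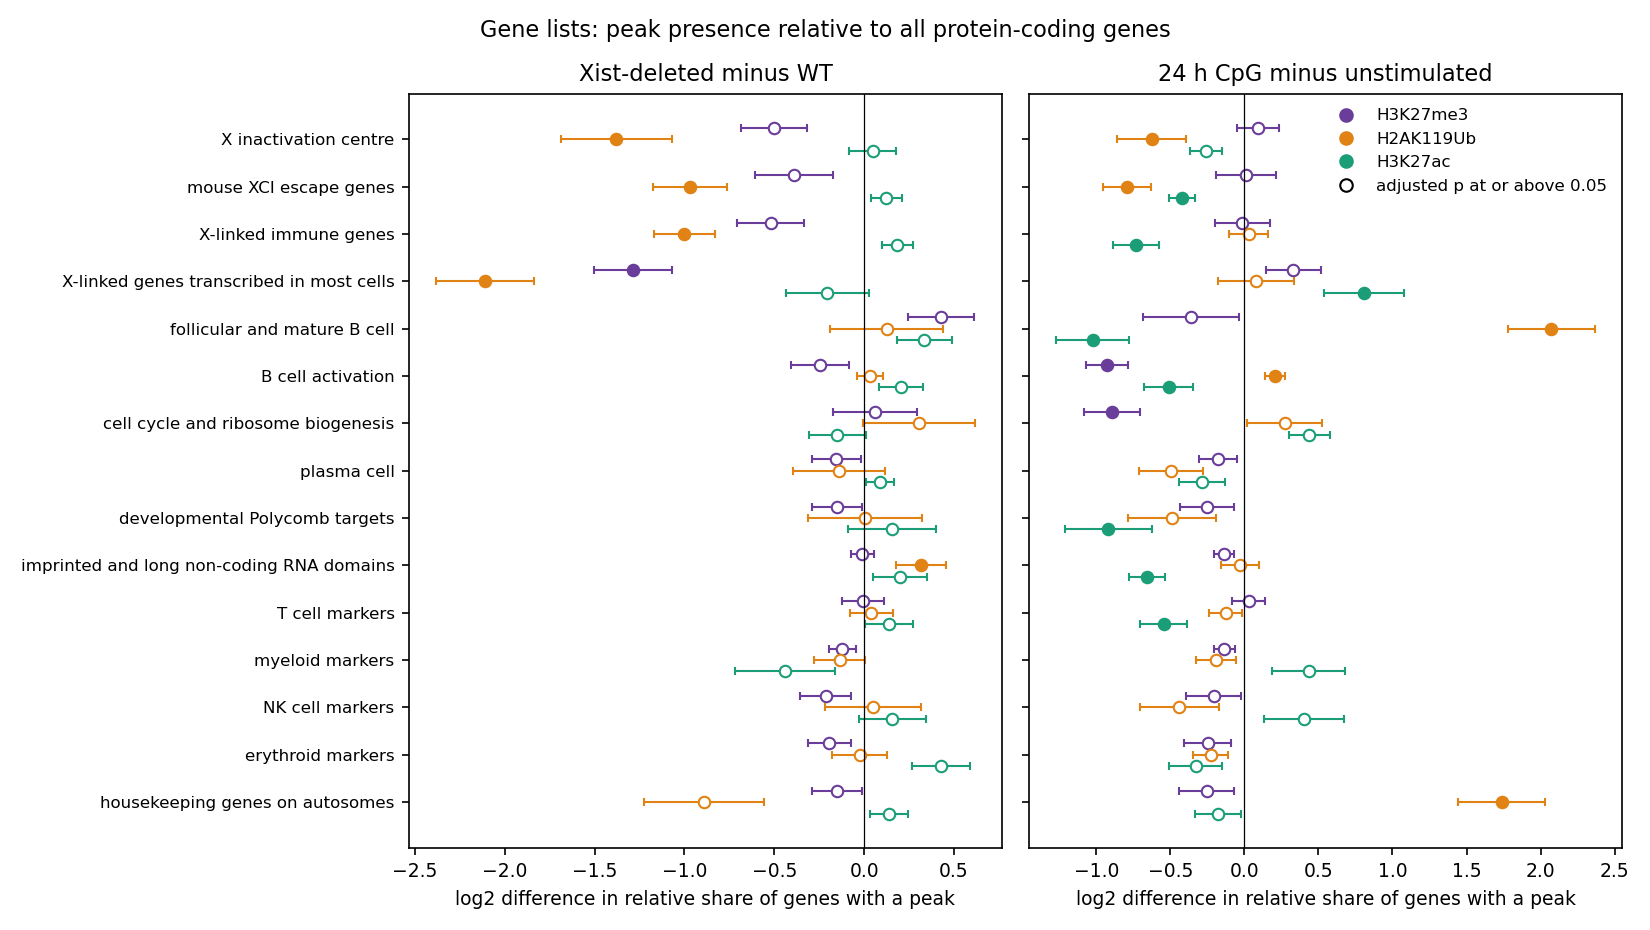
Difference in the share of a list's genes with a peak relative to all protein-coding genes (log2, horizontal axis) for each list and mark, between genotypes and between 24 h and 0 h; points are stratified differences, bars ± SE, and filled points have an adjusted p under 0.05 over 90 tests. X-linked genes transcribed in most cells were at −2.11 for H2AK119Ub and −1.29 for H3K27me3 between genotypes.

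Replicate lists overlapped by a mean Jaccard index of 0.500 ± 0.115 (SD over 40 pairs) for H3K27me3, 0.332 ± 0.085 (24 pairs) for H2AK119Ub and 0.566 ± 0.104 (24 pairs) for H3K27ac, counted as shared over joint bases. Between genotypes of the same system and time the means were 0.514, 0.342 and 0.555, each within 1 SD of the mean between replicates. No 2 libraries held identical lists, and the highest index between any pair of a mark was 0.711.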

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

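All tests of explanations in this part were chosen after the results were seen.

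H2AK119Ub on X was lower in Xist fl/fl than in WT cells at 24 h, and the difference exceeded that at 0 h by −2.55 ± 0.27 (SE) in the mb1-cre system and by −1.68 ± 0.36 in the TAT-Cre system, where only the 24 h cells had been given Cre, which is why it stands here as a difference between times. The number of peaks per list is argued against as the whole cause, since in lists of 1 length the mean difference at 24 h over both systems was −1.26 (exact permutation p = 0.005), against −2.40 before. A genotype difference present before Cre is argued against in the TAT-Cre system by the value of −1.68 (exact permutation p = 0.015 with times permuted), although in trimmed lists it was −0.57 ± 0.23 (exact permutation p = 0.27). In the mb1-cre system the difference at 0 h was −0.59, and loss of Xist and a prior difference between the mice cannot be told apart there, because no mb1-cre cells from before Cre were profiled. Loss of Xist in the TAT-Cre cells, which was not checked here, is a candidate explanation, and any effect of depth or antibody efficiency within the lists stays open.

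H3K27me3 on X differed more between genotypes in mb1-cre than in TAT-Cre cells at 24 h. The difference between systems was −1.41 ± 0.37 (exact permutation p = 0.0543) in deposited lists and −1.37 ± 0.53 (exact permutation p = 0.221) in lists of 1 length. Trimming hardly moved its size, but the test passed in neither, so list length is not excluded. The WT libraries themselves differed by 1.13 (mb1-cre minus TAT-Cre, exact permutation p = 0.0571; 0.99 and 0.0286, the smallest possible, in trimmed lists), and the Xist fl/fl libraries by −0.28 (exact permutation p = 0.229; −0.37 and 0.429 in trimmed lists). More of the difference thus lay in WT cells, and whether it comes from the libraries or from how the cells of each system were treated cannot be told apart.

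H3K27ac on X had genotype differences of opposite sign in the systems at 24 h, 0.62 ± 0.25 apart (exact permutation p = 0.01), which is why it stands here. List length is argued against, since in lists of 1 length the systems were 0.68 apart (exact permutation p = 0.03). A genotype difference present before Cre is consistent with the TAT-Cre values, which were −0.37 over 0 h and 24 h together (exact permutation p = 0.015) and changed by −0.01 ± 0.26 between the times. A difference between the mice used, unrelated to Xist, stays open.

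Among groups of at least 4 libraries, the median peak width of H3K27me3 mb1-cre WT 24 h replicate 1, 8508.5 bp, lay far from the others (10287 to 10483.5 bp). It was 1 of 20 such tests past the critical value, and chance gives about 1 in 20.

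Peaks on Y, which female cells lack, numbered 304 in 60 of 77 libraries, at most 20 in a library. Of these, 250 lay between 90717476 and 90838226 on Y and 54 elsewhere. A further 5147 of 883735 peaks lay on unplaced and patch sequences. Neither was used in a comparison, and no explanation was tested.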

How the results depend on the processing

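The settings with short H2AK119Ub lists left out, with either gene end and with time permuted were chosen after seeing the data. Of the X:autosome comparisons under other settings, 141 kept direction and side of the threshold, 13 reversed, 2 passed newly and 7 no longer passed. With 1 library left out, 202 kept both, 9 reversed and 2 no longer passed. Unless said otherwise, the cause was not tested.

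In trimmed lists the H3K27me3 difference was −1.11 for mb1-cre at 0 h (exact permutation p = 0.0159), 0.14 for the TAT-Cre baseline and −0.75 for stimulation of Xist fl/fl cells (exact permutation p = 0.0313). The H2AK119Ub baseline was −0.0754, and −0.16 and −0.10 with short lists left out and then trimmed; stimulation of WT cells was −0.0871. H3K27ac was 0.0754 for the pooled deletion and 0.33 for the TAT-Cre time difference. The lists at 0.0949 (X-linked immune) and −0.20 (imprinted) between genotypes, and −0.38 (housekeeping) on stimulation, were those reversed for H2AK119Ub, and −0.23 (X-linked broadly transcribed) and 0.18 (activation) for H3K27ac, where 15 list tests passed in place of 8. H3K27me3 gave 4 genes between genotypes.

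In the upper 50% of each list the H3K27me3 value was −1.28 for mb1-cre at 24 h (exact permutation p = 0.0571) and 0.16 for stimulation of Xist fl/fl cells. H3K27ac gave 0.10 for deletion, and 0.11 and 0.59 for stimulation of WT and Xist fl/fl cells. By share of signal the H3K27ac values were 0.0175, −0.21 and −0.16, and by number of peaks 0.0183, −0.0936 and −0.13. With replicate 5 at 24 h, H3K27me3 stimulation of Xist fl/fl cells was 0.0519. With times permuted the H2AK119Ub time differences of −2.55 and −1.68 had an exact p of 0.005 and 0.015.

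Correlations gave no sign that replicate numbers pair the libraries between times (38 pairs of 1 genotype and system, r from −0.288 to 0.210, in none of 12 comparisons all over 0.1). With so few libraries in a group this does not exclude a pairing. Between genotypes the correlations gave no such sign either (38 pairs, r from −0.603 to 0.656), except in H3K27ac of mb1-cre cells at 24 h. There all 3 pairs exceeded 0.1 (0.128 to 0.226) and correlated best with their own number. In that comparison the blocked difference was 0.25 (exact permutation p = 0.25, the smallest that 3 pairs can give), against 0.2 without it. With replicate number as a block, H3K27me3 for mb1-cre at 24 h stayed at −1.73 (exact permutation p = 0.125, the smallest that 4 pairs can give). H3K27ac stimulation of Xist fl/fl cells stayed at −0.28 (exact permutation p = 0.0938 over 6 pairs). Fewer permutations do not account for that value, since 6 pairs gave 0.03125 in WT cells. Stimulation genes were then 0, 828 and 313 for H3K27me3, H2AK119Ub and H3K27ac. In deposited lists they were 0, 2046 and 2483 (117 and 75 shared with the trimmed lists for the last 2), with no filter 9, 575 and 156, since more genes are tested, and by limma 103, 2389 and 1222. The upper 50% gave 635 for H2AK119Ub (388 shared). Between genotypes limma gave 1 gene for H3K27me3. Npm1 had 0 difference in H2AK119Ub in deposited lists. Replicate agreement by 1 bp overlap was 0.702, 0.497 and 0.741, and 0.468 for H2AK119Ub in trimmed lists.

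Leaving out 1 library, the values ran as follows. H3K27me3 differences ran from −1.04 to −0.45 (mb1-cre 0 h), −1.90 to −1.50 (24 h), −0.41 to −0.15 (TAT-Cre 24 h), −0.37 to 0.12 (baseline), −1.03 to −0.84 (pooled), 0.29 to 0.52 and −0.30 to −0.01 (stimulation, WT and Xist fl/fl), and −1.28 to −0.67 and −0.44 to 0.0454 (time differences). H2AK119Ub ran from −0.73 to −0.36, −3.23 to −3.05, −1.76 to −1.58, −0.20 to 0.28, −1.85 to −1.72, 0.98 to 1.17, −1.19 to −0.95, −2.77 to −2.40 and −1.96 to −1.48 in the same order. H3K27ac ran from 0.06 to 0.11, 0.12 to 0.33, −0.46 to −0.21, −0.51 to −0.26, −0.0520 to 0.0462, −0.41 to −0.29, −0.33 to −0.20, 0.03 to 0.24 and −0.11 to 0.15. Stimulation genes ran from 28 to 50, 1364 to 1493 and 496 to 593, and deletion genes stayed at 0 by the exact test. Windows at transcription starts were not run, and mb1-cre at 0 h has no value with short H2AK119Ub lists left out, since 1 WT library remains. Unknown depth limits any statement on absent peaks.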

Other observations

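The splits of the gene counts were chosen after those counts were seen, as was the use of an unadjusted p for X genes; the tests of kept genes and of the splits of X genes were written before their results were seen.

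In the window from 100 to 105 Mb, H3K27me3 covered 30.2% in mb1-cre WT cells at 24 h (15.3 to 50.8, n = 4) and 4.25% in Xist fl/fl cells (2.89 to 6.05, n = 4), and 4.29% and 4.04% in TAT-Cre cells. It was the window with the widest coverage in each of these groups. The window from 10 to 15 Mb, with Bcor, held 2.08% H3K27me3 in mb1-cre WT and 2.55% in Xist fl/fl cells. In both systems at 24 h, 17 X genes kept an H3K27me3 peak in every library, among them Bcor, Sowahd, Esx1 and Mid1, which also kept H2AK119Ub in every library.

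X genes that keep H2AK119Ub in Xist fl/fl cells may be those that also carry H3K27me3. Of the 143 X genes with H2AK119Ub in all mb1-cre WT libraries at 24 h, 49 kept a peak in at least 1 Xist fl/fl library, and 38 of these (77.6%) had H3K27me3 in most Xist fl/fl libraries, against 19 of 94 (20.2%) of those that lost it (Fisher's exact p = 4.17e-11). Kept here means a peak in at least 1 library, and 9 of the 49 genes had one in all 3 Xist fl/fl libraries. These libraries had a peak at 52, 32 and 14 X genes, in lists of 23425, 12808 and 9334 peaks. Neighbouring genes share peaks and are not independent. The genes that kept it were shorter (median 38.5 against 68.4 kb), so length does not account for more overlap by itself.

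Other splits of the libraries show how many genes a random division gives, made within system and time for genotype and within system and genotype for stimulation. For stimulation, only 1 of 100 splits, the real one, gave as many genes (44, 1247 and 499 for H3K27me3, H2AK119Ub and H3K27ac), and the highest other gave 0. The real split is 1 of the 100, so 1 is the fewest possible. This argues against a random division of the libraries as the source of these counts in trimmed lists. It does not cover the choice of setting, on which the H3K27me3 count depends (0 in deposited lists). For deletion the exact test called 0 genes in the real split (unadjusted 149, 177 and 70; limma 1, 0 and 0) and 0 in the highest other. A real count of 0 makes all 100 of 100 splits as large by construction, so this says nothing about chance. For X genes with fewer H2AK119Ub peaks at an unadjusted p under 0.05, the real split gave 81, the highest other 28, and 1 of 100 was as large. This argues against a random division there, in deposited lists. It does not separate genotype from list length, as mb1-cre lists at 24 h held 9334 to 23425 peaks in Xist fl/fl and 14806 to 32632 in WT cells. In trimmed lists 15 genes of all chromosomes had fewer H2AK119Ub peaks at that p, and the splits were not run on them. For H3K27me3 a random division is not argued against, since the real split gave 13, the highest other 27, and 6 of 100 were as large.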
